A study of Homo sapiens with 36 samples.

How the data were processed

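The series holds 36 samples of SUM-229PE cells, of which 22 are H3K27ac libraries, 4 are JUNB libraries and 10 are inputs. Per the labels, the subpopulations were separated by fluorescence-activated sorting for EpCAM and CD49f, chromatin was fixed with formaldehyde and sonicated, and libraries were amplified by PCR. Reads had no molecular identifiers described, so counts are of reads and not of independent molecules. Each sample was placed in its group by its title. The inputs have no column in the count tables and were not used here. The count columns of the acute trametinib arm carry another drug code, and were taken as that arm because their table is named for acute trametinib per the file headers and labels.

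The submitters' processing notes name cutadapt 1.12, STAR 2.5.2b, featureCounts, MACS2 and DESeq2 and the genome build hg19. The step each tool performed, the versions of featureCounts, MACS2 and DESeq2 and all settings are not given in the sources used here. The authors deposited 7 tables of whole-number counts per region and library, which are raw counts and not normalized. Each table has its own union of MACS2 regions, 1001 bases wide for H3K27ac and 201 bases for JUNB (end minus start). The authors also deposited 7 tables of DESeq2 results, whose log2 fold changes and standard errors rest on size factors computed by the authors. Adjusted p-values in these deposited tables are the authors' own, and some are missing. Missing values were left missing. All count columns were mapped to a sample. Coordinates are as the files give them, and no header says whether starts count from 0 or 1. The gene table held here is of the assembly GRCh38.p14 and no hg19 annotation or sequence was used, so regions were not assigned to genes, and the tests of gene lists and of sequence motifs were not run.

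Counts were tested with edgeR 4.0.16 (limma 3.58.1) in R 4.3.3. Library sizes were the counts in the regions, scaled by trimmed mean of M-values (TMM), with factors of 0.888 to 1.12 for H3K27ac and 0.961 to 1.07 for JUNB. Regions were filtered by edgeR's default filter with a minimum count of 10, and log values used a prior count of 2. The quasi-likelihood test was followed by Benjamini-Hochberg adjustment over the regions tested in each of the 10 tests, with a threshold of 0.05. Each comparison was fitted within its own table, with only the groups compared. POSR1 and POSR2 were entered as 1 group of 4 against POS, and were compared with each other in a fit that kept POS as a further group for the spread. Levels are CPM with TMM factors, and tables were normalized separately. Differences in response between NEG and POS were tested as an interaction over regions matched between tables. Regions of the same kind were matched 1 to 1 by a reciprocal overlap of 50%, and a JUNB site was assigned to an H3K27ac region where at least 50% of the site lay inside it. DESeq2 1.42.0 was run as an alternative test. Tables and plots were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

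Tests, groups, alternatives and the rule for named regions were fixed before the data were examined. By that rule, regions past the threshold, with a mean level at or above the median and with values that did not overlap between the groups, were ranked by absolute log2 fold change, and the first 8 higher and 8 lower were named. The part of the rule that asks for different nearest genes was not applied. In the POS and NEG comparison, for example, 22899 of 57023 tested regions met the criteria. Responses printed beside the interactions came from the interaction fits, a choice made after seeing the data. Regions named in the interactions, in all 4 trametinib comparisons, on chromosome 12 and by chromosome were chosen after their values were seen. The relations of chronic POS with chronic NEG and with POSR, the overlap of POSR1 and POSR2 calls and the set of regions moved one way in all 4 trametinib comparisons were added after the data were seen. Standard errors of correlations across regions came from a jackknife over chromosomes. For comparisons that share control libraries, 20 simulations of unchanged groups against those controls gave the value reached with no effect. Odds ratios matched on level used 5 groups of the level before treatment, by the Mantel-Haenszel method with 95% intervals.

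Depth was 4644625 to 8895187 counts in 57075 regions for POS against NEG, 4503760 to 9212006 in 50424 regions for acute POS, and 4711000 to 5179400 in 54454 regions for acute NEG. It was 3201383 to 5713610 in 44343 regions for chronic POS, 1861227 to 3617120 in 28239 for chronic NEG, 4537976 to 8908747 in 53549 for POSR, and 4884516 to 8947351 in 146555 for JUNB. Replicate pairs had a chi-square per degree of freedom of 1.10 to 4.79, and none was taken for a library deposited more than once. The test was tested on simulated data drawn from the means and library sizes of each comparison, with 200 changed regions. Of 2-fold changes it recovered 65% for POS against NEG (56933 regions), 79% for acute POS (50281), 71% for acute NEG (54355), 67% for chronic POS (44271) and 77% for chronic NEG (28122). Of 4-fold changes it recovered 91%, 94%, 96%, 96% and 96%. With only 200 changed regions the adjusted threshold was stricter than in the real data, so these shares do not measure recovery there. The alternatives were other scalings (relative log expression, total counts, loess offsets against abundance with a span of 0.3, factors per chromosome), no filter, DESeq2, a bound of 1 on the absolute log2 fold change, each library left out in turn, the replicate number as a block, and any overlap as the match.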

Results

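Chromatin immunoprecipitation followed by sequencing was performed in SUM-229PE, a triple-negative breast cancer cell line derived from a pleural effusion. The line was sorted into cells carrying the surface proteins EpCAM and CD49f (POS) and cells lacking both (NEG). Cells were given trametinib, an inhibitor of the kinase MEK, at 30 nM for 24 hours (acute) or at 10 nM for 14 days (chronic). The acetylated histone mark H3K27ac, found at active promoters and enhancers, was profiled in 22 libraries, and JUNB, a subunit of the AP-1 transcription factor, in 4. The H3K27ac groups were acute DMSO (3 POS, 2 NEG), acute trametinib (3 POS, 2 NEG), chronic day 0 and day 14 (2 each for POS and NEG), and POSR1 and POSR2 (2 each). The labels do not say what POSR1 and POSR2 are, or whether they were under drug when collected. JUNB was profiled in untreated POS (2) and NEG (2) cells. H3K27ac libraries held 1861227 to 9212006 counts in the listed regions, with a median of 43 to 91 counts per region, and JUNB libraries held 4884516 to 8947351, with a median of 17 to 27. Replicates of a group correlated across regions with r of 0.935 to 0.982, and in each pair they differed by more than sampling noise. No label says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Coordinates are hg19, and regions were not assigned to genes here.

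POS and NEG cells carried largely different H3K27ac landscapes before treatment. Of 57023 regions tested, 22001 were higher in POS and 21648 higher in NEG, and in 33903 regions the difference was 2-fold or more (17494 higher in POS, 16409 higher in NEG). At chr3:13894701-13895702, H3K27ac was 45.9 ± 7.98 CPM (counts scaled to a common library size; SD, n = 3) in POS and 0.178 ± 0.00041 (n = 2) in NEG. At chr2:218763054-218764055 it was 116 ± 21.4 CPM in POS and 0.533 ± 0.25 in NEG. The region chrX:32895732-32896733 had 17.1 ± 2.03 CPM in POS and no count in NEG, which made it at least 64.1-fold higher in POS, against a floor of 3 counts over the group. In the other direction, chr6:68599079-68600080 had 46.1 ± 4.25 CPM in NEG and 0.245 ± 0.218 in POS, and chr6:68339390-68340391 had 126 ± 5.49 in NEG and 0.866 ± 0.155 in POS. Such floors cover counting error only, whereas SDs are between libraries. The 8 named regions lower in POS had log2 fold changes of -6.75 to -7.64, and 7 of them held a JUNB site that was higher in NEG. Among the 8 named regions higher in POS, 7 held a JUNB site that was higher in POS. These calls were made by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the highest adjusted p among the 8 regions higher in POS was 4.5e-16. The authors' deposited table for this comparison called 32503 regions, of which 99.99% were also called here, all in the same direction.

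**Figure D1:**
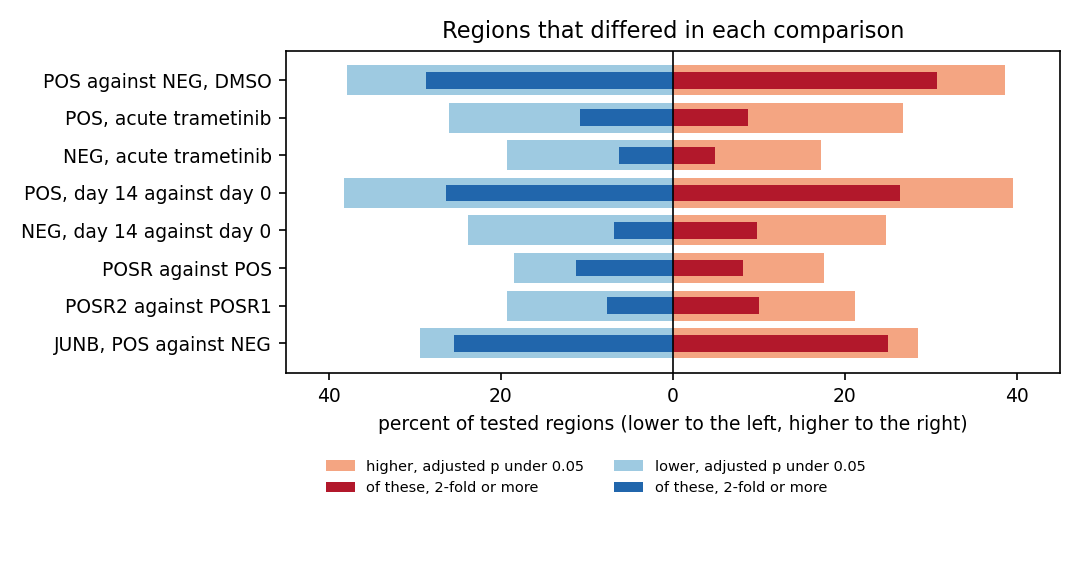
Percent of tested regions that differed in each comparison (horizontal axis, lower to the left and higher to the right of 0); light bars are regions with an adjusted p under 0.05 and dark bars those that were also 2-fold or more apart. The share was 77.8% for the day 14 response of POS, 76.5% for POS against NEG, and 36.1% for POSR against POS with POSR1 and POSR2 taken as 1 group.

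JUNB binding also differed between the untreated subpopulations. Of 141580 sites tested, 40350 were higher in POS and 41594 higher in NEG, and 71592 differed 2-fold or more. The strongest named sites were bound in one subpopulation with no count in the other. In NEG, chr10:44304755-44304956 had 30.8 ± 3.77 CPM (n = 2) and was at least 141-fold higher than in POS, and chr10:44547250-44547451 was at least 118-fold higher. In POS, chr10:123339290-123339491 had 18.1 ± 3.58 CPM (n = 2) and was at least 85.1-fold higher than in NEG. H3K27ac at that POS site was also higher in POS, with a log2 fold change of 5.10 ± 0.35 (SE). In 43997 H3K27ac regions that held a JUNB site, the site with the highest mean level was taken for each. The log2 fold changes of JUNB and H3K27ac correlated with r = 0.870 ± 0.0026 (jackknife SE over 23 chromosomes). This is a correlation across regions, which are not independent replicates, and was the closest of 10 such relations computed between comparisons. Of 26141 pairs in which both marks passed the test, 25213 (96.4%) moved the same way. Both were higher in POS in 13212 pairs, against 6394 if the lists were independent, and both were higher in NEG in 12001, against 5432. Among H3K27ac regions higher in POS by 2-fold or more, 63.6% held a JUNB site higher in POS and 0.737% one higher in NEG. Among those higher in NEG, 58.0% held a JUNB site higher in NEG and 0.152% one higher in POS. On simulated data of this design, 13% of JUNB sites changed 2-fold and 65% of those changed 4-fold were recovered. With only 200 changed sites the adjusted threshold was stricter than in the real data. These shares therefore do not measure recovery there.

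The response of POS cells to 24 hours of trametinib was read from 3 treated and 3 DMSO libraries. H3K27ac rose in 13457 and fell in 13096 of 50345 regions, and changed 2-fold or more in 9871 (4408 higher, 5463 lower). The largest named losses exceeded the largest named gains. At chr17:62702044-62703045, H3K27ac dropped from 124 ± 23.1 to 5.28 ± 1.48 CPM (SD, n = 3 each), a log2 fold change of -4.60 ± 0.21 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.3e-34). At chr6:86173883-86174884 it dropped from 76.8 ± 14.1 to 3.25 ± 0.488 CPM, and at chr3:102017897-102018898 from 62.8 ± 10.0 to 3.11 ± 0.424. Gains included chr13:106469305-106470306, which rose from 1.85 ± 0.688 to 20.3 ± 1.01 CPM, and chr1:182771122-182772123, which rose from 3.06 ± 0.723 to 31.7 ± 1.00. The 8 named gains ran from 2.87 to 3.50 on the log2 scale and the 8 named losses from -4.08 to -4.60. A JUNB site of untreated cells lay in 7 of the 8 losses and in 2 of the 8 gains. The authors' deposited table called 19924 regions, of which 98.0% were also called here.

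In NEG cells the same treatment, with 2 libraries per group, raised H3K27ac in 9351 and lowered it in 10527 of 54409 regions. In 6080 of these the change was 2-fold or more (2692 higher, 3388 lower). At chr2:212916417-212917418, H3K27ac dropped from 77.8 ± 0.131 to 8.98 ± 0.12 CPM (SD, n = 2 each), with a log2 fold change of -3.11 ± 0.15 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.6e-91). The same region also fell in POS, by a log2 fold change of -3.56 ± 0.17 after acute and -3.38 ± 0.27 after chronic treatment. At chr9:6552084-6553085, where POS over NEG had a log2 fold change of -4.08 ± 0.20 before treatment, it dropped from 66.6 ± 8.43 to 7.95 ± 0.759 CPM. The largest named gain was chr18:2009339-2010340, from 2.49 ± 0.136 to 19.1 ± 1.33 CPM, followed by chr2:139086577-139087578, from 3.58 ± 0.288 to 25.9 ± 0.0578 CPM. A JUNB site of untreated cells lay in 6 of the 8 named losses and 2 of the 8 named gains, and 5 of the sites in losses were higher in NEG. DESeq2 called 10146 regions. The authors' deposited table, in which 14781 adjusted p-values are missing, called 6192, all of which were also called here.

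Acute responses of POS and NEG overlapped, and a minority of regions responded differently. Over 18184 regions matched between the tables, the log2 fold changes correlated with r = 0.648 ± 0.0075. Of 5618 regions that passed the test in both, 5174 (92.1%) moved the same way. Both rose in 1718, against 717 if the lists were independent, and both fell in 3456, against 1644. The difference of the responses was tested as an interaction in 18186 regions, and 4650 (25.6%) differed. With both responses taken from the same fit as the interaction, 506 (10.9%) of these moved in opposite directions. In 249 regions H3K27ac fell in POS and rose in NEG, and in 257 it rose in POS and fell in NEG, while on the separate scales of the acute POS and NEG tables the counts were 279 and 165. In a further 988 a fall passed the test only in POS, in 936 a gain only in POS, in 523 a gain only in NEG and in 474 a fall only in NEG. At chr8:8146526-8147527, the log2 fold change in that fit was -2.88 in POS and 0.47 in NEG, a difference of 3.35 ± 0.25 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 8.7e-19). At chr20:55622122-55623123 it was 1.17 in POS and -1.53 in NEG, a difference of -2.69 ± 0.19.

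After 14 days at the lower dose, most H3K27ac regions of POS cells had changed. No day 14 group without drug was profiled. In all day 14 comparisons, here called chronic responses, drug and time in culture therefore cannot be told apart. Of 44304 regions, 17522 were higher and 16927 lower at day 14 than at day 0 (n = 2 each), and 23422 had changed 2-fold or more, 11711 in each direction. At chr14:22965984-22966985, H3K27ac rose from 0.656 ± 0.0817 to 62.8 ± 0.699 CPM, with a log2 fold change of 6.50 ± 0.28 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.5e-50). Another region on the same chromosome, chr14:22990829-22991830, rose from 2.48 ± 0.727 to 122 ± 2.49 CPM, and chr22:31588475-31589476 rose from 1.58 ± 0.724 to 77.7 ± 2.35. None of the 8 named gains held a JUNB site of untreated cells. The named losses included chr13:75465767-75466768, from 55.8 ± 0.149 to 1.05 ± 0.179 CPM, and chr3:99262042-99263043, from 64.4 ± 9.86 to 1.25 ± 0.456. A JUNB site lay in 7 of the 8 named losses. The authors' deposited table called 23963 regions, of which 99.99% were also called here.

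In NEG cells, 6994 regions were higher and 6704 lower at day 14 among 28179 tested (n = 2 each), and 4687 had changed 2-fold or more (2768 higher, 1919 lower). The largest named gain was chr15:35654231-35655232, from 6.11 ± 0.616 to 92.0 ± 0.486 CPM, a log2 fold change of 3.92 ± 0.19 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.3e-29). That region had also risen in NEG after acute treatment, with a log2 fold change of 2.57 ± 0.17. Next came chr7:131085210-131086211, from 6.20 ± 0.0574 to 70.8 ± 8.60 CPM. The largest named loss was chr3:30398200-30399201, from 67.9 ± 3.94 to 7.31 ± 0.826 CPM, and this region had fallen after acute treatment in both POS (-1.39 ± 0.15) and NEG (-2.27 ± 0.15). At chr8:120677168-120678169, H3K27ac dropped from 128 ± 0.218 to 20.2 ± 4.03 CPM. DESeq2 called 7501 regions. The authors' deposited table, in which 548 adjusted p-values are missing, called 4520, all of which were also called here.

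The chronic responses of POS and NEG overlapped and also differed. Over 15789 matched regions the log2 fold changes correlated with r = 0.454 ± 0.0058, a relation added after the data were seen, and 4905 (76.3%) of 6432 regions called in both moved the same way on the separate scales of the tables. The interaction was called in 9891 of 15794 matched regions (62.6%), a set matched and fitted separately from the acute one, and 1503 (15.2%) of these moved in opposite directions on the scale of that fit. H3K27ac fell in POS and rose in NEG in 754 regions and did the reverse in 749, while on the separate scales of the chronic POS and NEG tables the counts were 1141 and 316. In 2197 regions a fall passed the test only in POS, in 2578 a gain only in POS, in 438 a fall only in NEG and in 466 a gain only in NEG. At chr3:139021078-139022079, the log2 fold change on the scale of that fit was -4.39 in POS and 0.52 in NEG, a difference of 4.91 ± 0.26 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.4e-78). At chr8:67383058-67384059 it was -2.03 in POS and 2.28 in NEG. At chr20:55622591-55623592, which overlaps the acute example, it was 2.24 in POS and -1.71 in NEG, a difference of -3.95 ± 0.19. The response was higher in NEG in 50.9% of the called regions. That split moved to 65.6% when libraries were scaled by total counts and to 75.7% with the factors of each full table, settings that shifted the median of all regions by 0.32 and 0.52 on the log2 scale.

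Within each subpopulation the acute and chronic responses shared many regions. In POS the log2 fold changes correlated with r = 0.712 ± 0.0030 over 30736 matched regions, and 13237 (89.0%) of the 14866 that passed both tests moved the same way. Both were higher in 6089, against 3092 if the lists were independent, and both lower in 7148, against 3785. In NEG the correlation was 0.629 ± 0.0064 over 19039 regions, and 5381 (90.7%) of 5936 moved the same way. A set of 10372 regions was matched in all 4 trametinib comparisons, which share no libraries. H3K27ac was lower in all 4 in 1248 of them, against 180 if the comparisons were independent, and higher in all 4 in 344, against 18.5. At chr14:28777417-28778418, the log2 fold changes were -2.41 ± 0.15 in acute POS, -2.29 ± 0.12 in acute NEG, -4.53 ± 0.24 in chronic POS and -2.10 ± 0.13 in chronic NEG. At chr22:33184837-33185838 they were 1.76, 1.66, 4.09 and 2.10 in the same order. A JUNB site of untreated cells lay in 96.7% of the regions lower in all 4 and in 94.8% of those higher in all 4, against 92.3% of the other 8780.

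**Figure D2:**
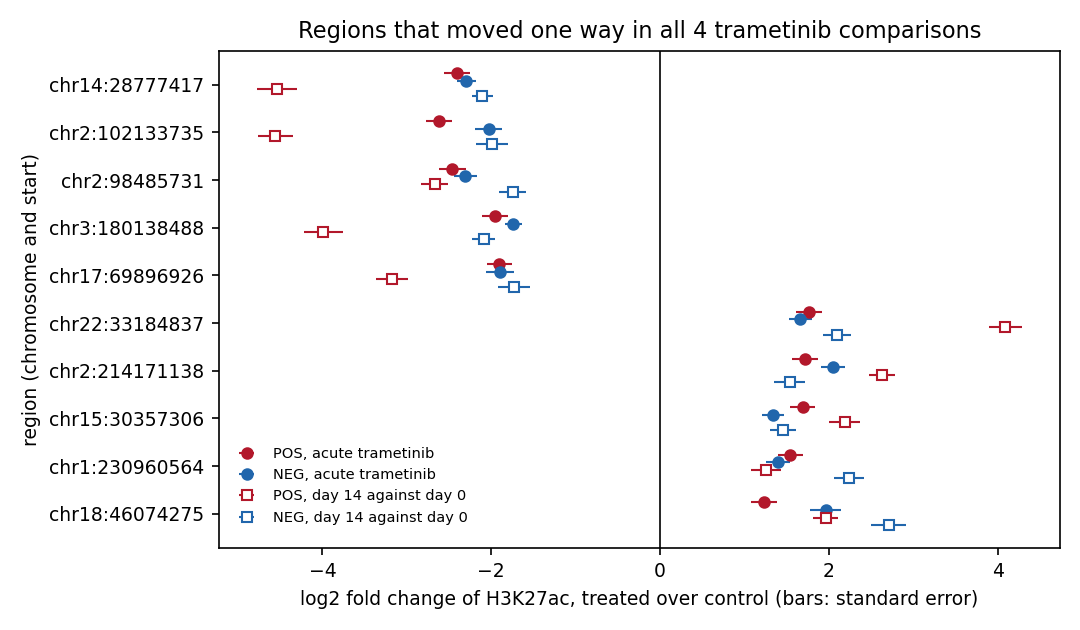
Log2 fold change of H3K27ac with its standard error (horizontal axis) at 5 regions lower and 5 higher in all 4 trametinib comparisons, each named by chromosome and start (vertical axis); circles are acute, open squares day 14, red POS and blue NEG. At the region starting at 28777417 on chromosome 14 the day 14 value of POS (-4.53) lay furthest from 0, while the other 3 values lay between -2.10 and -2.41.

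Regions that lost H3K27ac after trametinib more often held a JUNB site of untreated cells, from either POS or NEG, than regions that gained it. After acute treatment, a site lay in 91.3% of regions lower by 2-fold or more in POS and 62.1% of those higher, and in NEG in 89.5% and 54.9%. At day 14 the shares were 90.5% and 53.0% in POS, and 84.7% and 67.1% in NEG. Sites 2-fold or more higher in POS, taken alone, lay more often in the higher than in the lower regions in each comparison. Regions that did not pass the test held a site in 70.7% (acute POS), 50.3% (acute NEG), 81.0% (chronic POS) and 79.3% (chronic NEG). Lost regions were mostly strong before treatment, and strong regions held sites more often. In acute POS, 1637 lower and 239 higher regions lay in the strongest of 5 groups by level before treatment, where 95.7% and 92.9% held a site. In the weakest group, 356 were lower and 1945 higher, and 62.1% and 37.5% held a site. Comparing lower with higher regions within these 5 level groups brought the odds ratio from 6.37 to 2.42 in acute POS, from 7.01 to 1.74 in acute NEG, from 8.44 to 2.03 in chronic POS and from 2.72 to 0.944 in chronic NEG. The 95% intervals were 2.12 to 2.76, 1.46 to 2.08, 1.85 to 2.22 and 0.772 to 1.16. They take regions as independent, although neighbouring regions moved together, so they may be too narrow.

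**Figure D3:**
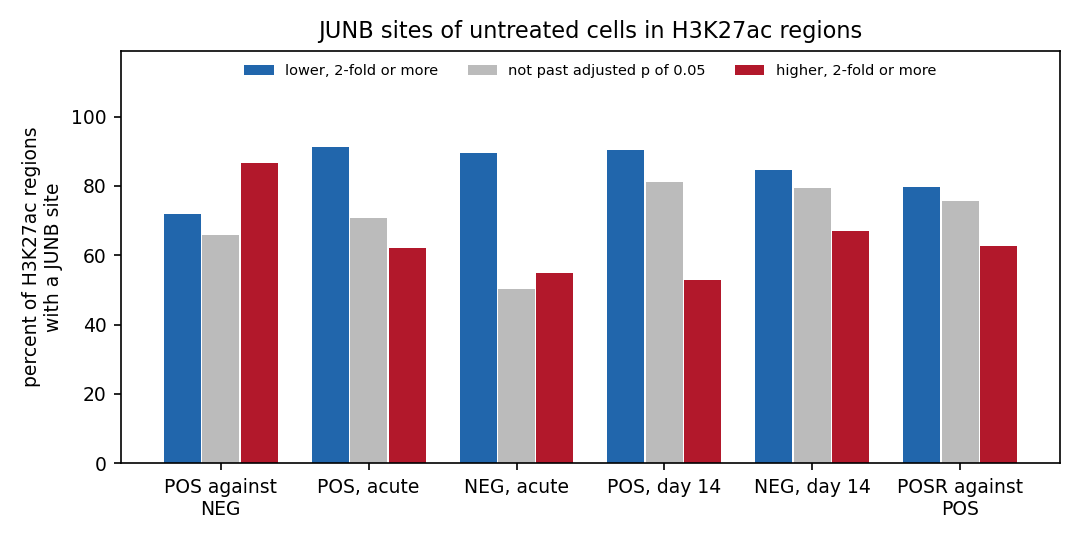
Percent of H3K27ac regions that hold a JUNB site of untreated cells (vertical axis) among regions lower by 2-fold or more, not past an adjusted p of 0.05, or higher by 2-fold or more, in 6 comparisons (horizontal axis). In each of the 4 trametinib comparisons the lower regions have the highest share, from 84.7% to 91.3%.

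POSR1 and POSR2 were compared with untreated POS as 1 group of 4. Of 53240 regions, 9331 were higher and 9873 lower in POSR, and 10360 differed 2-fold or more (4366 higher, 5994 lower). At chr19:28349138-28350139, H3K27ac was 30.9 ± 11.6 CPM in POSR (SD, n = 4) and 0.287 ± 0.262 in POS (n = 3), a log2 fold change of 6.84 ± 0.53 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 5.6e-05). Another region of the same chromosome, chr19:28463151-28464152, had 29.3 ± 5.27 and 0.413 ± 0.394 CPM. Among losses, chr15:62086503-62087504 had 2.40 ± 0.328 CPM in POSR, where POSR1 replicate 2 was lowest at 1.91, and 72.9 ± 11.2 in POS. That region had also fallen in all 4 trametinib comparisons, with log2 fold changes of -3.54 ± 0.18 and -4.14 ± 0.22 in acute and chronic POS and -2.33 ± 0.11 and -1.49 ± 0.12 in acute and chronic NEG. The loss at chr7:43424841-43425842, from 39.7 ± 2.79 to 1.73 ± 0.574 CPM, was accompanied by falls in POS after acute (-3.16 ± 0.17) and chronic (-3.39 ± 0.20) treatment. The authors' deposited table called 19187 regions, of which 94.8% were also called here. Without POS DMSO replicate 3, 11293 regions were called, with the replicate number as a block 6527, with POSR2 alone 29760, and with POSR1 and POSR2 as groups of their own 31919. On simulated data of this design 15% of 2-fold and 84% of 4-fold changes were recovered, with only 200 changed regions. These shares do not measure recovery in the real data.

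POSR1 and POSR2 differed from each other in 21671 of 53524 regions, 11337 higher and 10334 lower in POSR2, with 9463 regions 2-fold or more apart. At chr7:70193932-70194933, H3K27ac was 35.2 ± 0.203 CPM in POSR2 and 0.411 ± 0.412 in POSR1 (n = 2 each), a log2 fold change of 6.44 ± 0.29 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 4.7e-106). Among the regions that met the naming rule, the opposite difference was largest at chr11:75741418-75742419, with 1.11 ± 0.458 CPM in POSR2 and 20.8 ± 2.18 in POSR1. Their differences from POS nevertheless overlapped. Over 53151 regions tested in both, 28446 were called in POSR1 and 29526 in POSR2 against POS. Of 19693 regions called in both POSR1 and POSR2 against POS, 18202 (92.4%) moved the same way. Both were higher in 8189, against 3563 if the lists were independent, and both lower in 10013, against 4355. The 2 comparisons use the same POS libraries. Their correlation was 0.675, and unchanged groups simulated against those libraries gave 0.434. The covariance was 0.597 against a simulated 0.0231. With the 3 POS libraries divided between the comparisons, so that none was shared, the correlation was 0.575 to 0.642 over the 6 ways of dividing them, and 87.6% to 92.9% of regions called in both moved the same way. Such divisions were chosen after the values were seen.

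A stretch of chromosome 12 stood out in POSR, chosen for description after the values were seen. Between 24948440 and 26145759, H3K27ac was 2-fold or more higher in POSR in 44 of 46 neighbouring regions, with a median log2 fold change of 2.66. The median level over the stretch was 9.16, 13.1 and 11.4 CPM in the 3 POS libraries, 66.3 and 60.1 in POSR1, and 44.1 and 42.4 in POSR2. The largest change was at chr12:25395248-25396249, with 172 ± 34.9 CPM in POSR (SD, n = 4) and 8.97 ± 2.57 in POS (n = 3). POSR1 and POSR2 differed along the stretch. In 7 regions from 24948440 to 25101165 the median log2 ratio to POS was 2.86 in POSR2 and -0.14 in POSR1. The 19 regions from 25170281 to 25539463 were the longest run 2-fold or more higher in both, and the parts were divided by this rule. Their medians were 3.42 in POSR1 and 2.64 in POSR2. In 20 regions from 25588783 to 26145759 the medians were 2.72 in POSR1 and 1.03 in POSR2. The end of the stretch was set by the rule that found it, and a further stretch followed from 26163005 to 26647561, with 14 of 16 regions 2-fold or more higher and a median log2 fold change of 1.48. POS and NEG cells before treatment did not differ as a block there, with a median log2 fold change of -0.13 over 27 matched regions.

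**Figure D4:**
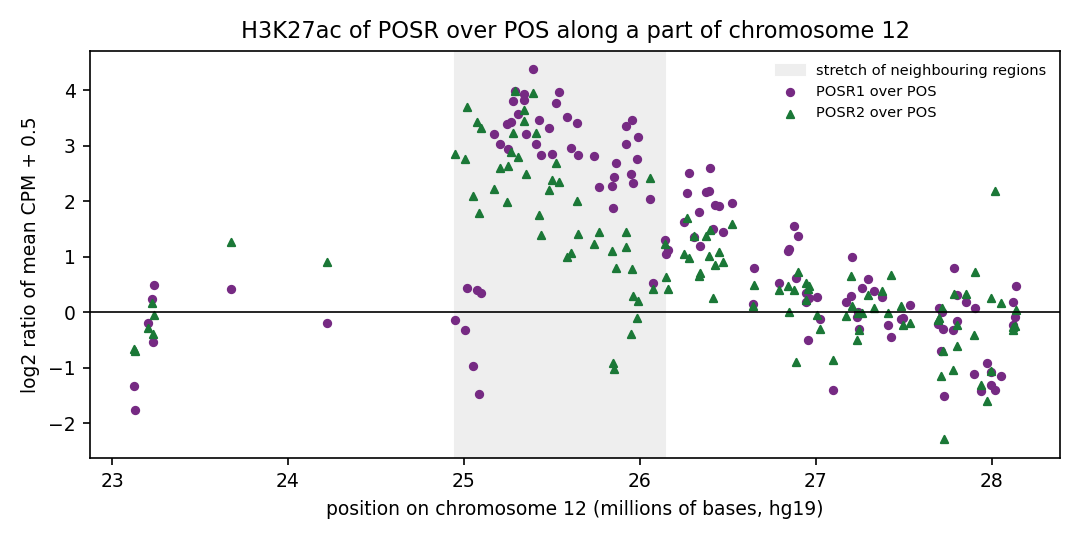
Log2 ratio of mean H3K27ac (CPM + 0.5) to untreated POS (vertical axis) for each region by its position on chromosome 12 in megabases (horizontal axis), with POSR1 as purple circles and POSR2 as green triangles; the grey band is the stretch from 24948440 to 26145759. POSR2 is raised (median 2.86) and POSR1 is not (-0.14) at the left end of the band, both are raised in the 19 regions that follow, and POSR2 drops to a median of 1.03 at the right end.

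The POSR differences were also set beside the trametinib responses of POS. The labels give POSR1 and POSR2 no drug, dose or time. Whether a shared direction was a response to drug present at collection therefore cannot be told. With the acute response, which uses the same POS DMSO libraries, r was 0.416 ± 0.0090 over 40826 regions, and 7605 (79.5%) of 9569 regions called in both moved the same way. Both were higher in 2761, against 1663 if the lists were independent, and both lower in 4844, against 2759. Unchanged groups simulated against the shared libraries gave r = 0.545, above the 0.405 observed on the same regions, while the observed covariance was 0.267 against a simulated 0.0383. With the POS libraries divided between the comparisons in each of 6 ways, r was 0.289 to 0.417, and 70.7% to 88.2% of regions called in both moved the same way. The chronic response of POS shares no libraries with POSR, and this relation was added after the data were seen. With it, r was 0.449 over 30986 regions, and 79.4% of 9402 regions called in both moved the same way (both higher in 3314, against 2003 if independent, and both lower in 4150, against 2477). Acute NEG, chronic POS and chronic NEG share no libraries with POSR against POS, and this set of 3 was chosen after the values were seen. Of regions lower in all 3, 670 of 1516 (44.2%) were lower in POSR and 5.61% higher, and of those higher in all 3, 226 of 505 (44.8%) were higher and 3.56% lower. Of the other 8026 matched regions, 16.7% were lower and 22.4% higher in POSR. With the difference between POS and NEG the POSR difference had r = -0.037 ± 0.019 over 38196 regions, and 43.5% of 11302 regions called in both had the same sign. The simulated value for that pair was -0.451, and its covariance of -0.0395 was close to the simulated -0.0401. With the POS libraries divided, r ran from -0.107 to 0.0580 and so changed sign with the division.

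Differences between POS and NEG were not spread evenly over the chromosomes, which was examined after the values were seen. The median log2 fold change of POS over NEG was 0.87 on chromosome 13, 0.71 on chromosome 9, 0.51 on chromosome 14 and 0.49 on chromosome 1. It was -0.75 on chromosome 8, -0.53 on chromosome 19, -0.48 on chromosome 21 and -0.47 on chromosome 5. JUNB sites outside H3K27ac regions (89617 sites) had medians of 0.86, 0.59, 0.52 and 0.12 on the former 4 chromosomes and -0.25, -0.77, -0.29 and -0.04 on the latter 4. Across 23 chromosomes the H3K27ac and JUNB medians correlated with Pearson's r = 0.820 and Spearman's rho = 0.8291 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). Without the 2 chromosomes farthest from the median, r was 0.793. In POSR, chromosome 19 had a median of 0.53 over POS, with 39.8% of its 1049 regions called higher and 5.53% lower. Both comparisons use the same POS libraries, so this value and the -0.53 of POS over NEG are not independent.

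**Figure D5:**
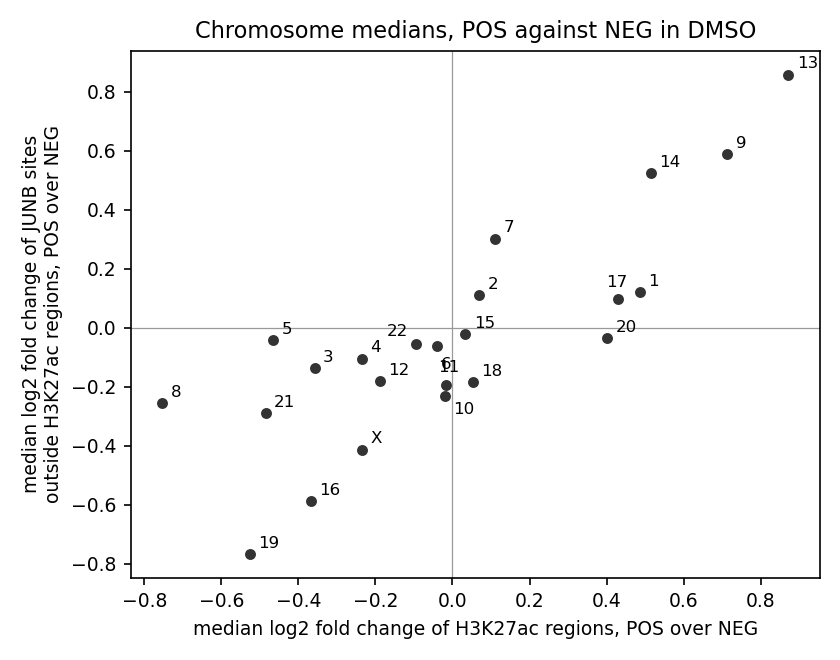
Median log2 fold change of POS over NEG per chromosome for H3K27ac regions (horizontal axis) and for JUNB sites outside H3K27ac regions (vertical axis), each point a chromosome named by its number or letter. Chromosome 13 lies highest on both axes (0.87 and 0.86), and the 23 points correlate with r = 0.820.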

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

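The loess tests of the response difference, with the count of regions called in both fits, were chosen only after the result was seen; the tests of the starting level, of JUNB binding and of other splits of the libraries were planned. By an interaction test, H3K27ac responded differently in NEG and POS in 4650 of 18186 matched regions after acute trametinib. The change from day 0 to day 14 under trametinib differed in 9891 of 15794, where drug and time in culture cannot be told apart. A weak starting level in one subpopulation does not account for this. Among regions whose level before treatment differed by under 0.5 log2 units, 22.6% of 7075 were called in the acute comparison against 27.5% of the other 11111, a ratio of 0.823 (95% interval 0.775 to 0.872), and in the chronic one the ratio was 1.03 (0.995 to 1.06). ChIP efficiency that varies with the level of a region is also argued against as the whole cause, since with loess offsets 5589 and 9755 regions were called, among them 4625 of the 4650 and 8540 of the 9891 in the same direction. In the acute comparison, no deeper loss was seen in the subpopulation with more JUNB at a region before treatment. The response difference (NEG minus POS) was rank-correlated with the JUNB difference (POS minus NEG) across 15074 regions. Within 5 groups of the H3K27ac difference before treatment, the mean correlation was -0.0282 (-0.0439 to -0.0125), with groups from -0.0762 to 0.0405. Because JUNB and H3K27ac differences correlate, that grouping removes part of the JUNB contrast. Without groups the correlation was 0.00218. A difference between POS and NEG cells may underlie the pattern and stays open, untested, beside differences between the cultures or handling of the arms, and the share of regions in which NEG responded higher in the chronic comparison moved with the scaling.

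At chr15:62086503-62087504, one POSR library lay apart from the other 3. The values were 1.91 CPM in POSR1 replicate 2 and 2.51, 2.53 and 2.63 in the others, and its gap was 0.841 of the range. Of 17 groups of 4 examined, 1 was set apart in this way, and chance does so in about 1 in 20.

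Other splits of the libraries were fitted for the comparisons with at least 3 libraries per group. For POSR against POS, 1 of the 35 splits of the 7 libraries, the real one, called as many as 19204 regions. This share is under 0.05 but takes each library as independent, which no label states, so it cannot exclude chance. POSR1 and POSR2 differ from each other in 21671 regions, and with POSR1, POSR2 and POS taken as 3 sets the splits are too few for a share under 0.05. The highest of the others called 0 by edgeR's quasi-likelihood test, and at most 13892 at an unadjusted p under 0.05, against 24569 in the real split. For acute POS the 10 splits are too few for a share under 0.05. Of these 10, 1 called as many as 26553 regions, the real one, and the highest of the others called 0, and at most 1789 at an unadjusted p under 0.05, against 28884.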

How the results depend on the processing

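The factors of each full table, the unblocked fit on shared replicate numbers and the divided POS libraries were chosen after seeing the data. Of the alternatives other than leaving out a library, 70 counts of called regions lay within 1.5 times the reported one and 13 did not, and all 20 alternatives of matching or scaling for correlations across regions kept their direction. With the POS libraries divided between comparisons in 6 ways, the correlation of POSR with POS against NEG, reported as -0.037, turned positive in 2 (0.0580 and 0.0408) and reached -0.107, and that with acute POS moved in 4 (0.289, 0.290, 0.390 and 0.393), and the cause was not tested. Named regions kept direction and side of the threshold in all 160 cases under each of relative log expression, total counts, loess offsets and DESeq2. A 2-fold bound left 9871 regions in acute POS, 6080 in acute NEG, 4687 in chronic NEG, 10360 in POSR against POS, 9463 between POSR2 and POSR1, and 1777 and 6116 in the acute and chronic interactions, as fewer regions can pass. DESeq2 called 10146 regions in acute NEG and 7501 in chronic NEG, and the cause was not tested. For POSR against POS, POSR2 alone gave 29760 and separate POSR groups 31919, since the difference between POSR1 and POSR2 then leaves the residual spread. Total counts shifted the median of POS over NEG by -0.16 on the log2 scale, and leaving out NEG JUNB replicate 1 shifted that of JUNB by 0.10.

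With each library left out in turn, counts ran from 37407 to 46052 for POS against NEG, 22670 to 27714 for acute POS, 15255 to 16979 for acute NEG, 29156 to 34804 for chronic POS, 10805 to 12893 for chronic NEG, 11293 to 18273 for POSR, 62675 to 73772 for JUNB, 14526 to 16342 between POSR2 and POSR1, and 3392 to 5294 and 9000 to 9764 for the interactions. The lowest POSR value came without POS DMSO replicate 3, and the cause was not tested. Groups left with 1 library were assumed to vary like the other groups.

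Replicate numbers were not taken to pair samples. In acute POS the same-number deviations correlated at 0.12, 0.38 and -0.016, and 1 of the 3 numbers correlated best with its own. With the replicate block, 37348 (POS against NEG), 28862, 19697, 33843 and 13627 (acute POS and NEG, chronic POS and NEG), 82847 (JUNB), 18490 (POSR2 against POSR1), 5457 and 9819 (interactions) regions were called. For POSR the replicate block gave 6527, against 11293 without it on the same libraries.

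The planned tests of gene lists and sequence motifs, with their alternatives, were not run, as no hg19 annotation or sequence was used here. Median counts per region were 43 to 91 for H3K27ac and 17 to 27 for JUNB.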

Other observations

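The runs and stretches of neighbouring regions, the count of regions called with and without factors per chromosome, the windows weak in POS, the choice of regions on 2 POS libraries, the 100 level groups, the chromosome correlation, the factors per chromosome as a test of copy number and the chromosome 12 test were chosen only after the results were seen; the JUNB tests within 5 level groups and the quartile test were planned. A minority of runs of at least 5 closely spaced regions were counted as lower or higher. Such a run had at least 5 regions called 2-fold or more one way and none the other way. Its other regions could be unchanged or move by less in either direction. In the single runs described by position, regions called at any size were counted. In acute POS, 11 of 810 runs were lower by the 2-fold rule, against a mean of 0.189 when fold changes were shuffled, and 0 higher. In POS against NEG, 117 of 1038 were lower and 63 higher, against 9.39 and 9.41. In chronic POS, 29 of 521 runs were lower and 15 higher, against 2.27 and 2.03. In acute NEG, 10 of 1292 were lower and 2 higher, against 0.109 and 0.022. In chronic NEG, 0 of 300 were lower by the 2-fold rule and 2 higher, no more than the highest of 1000 shuffles. In POSR against POS, 13 of 824 were lower and 4 higher, against 0.294 and 0.091. On chromosome 12 from 66042191 to 66090306, all 6 regions fell in acute POS (median log2 fold change -3.05), and all matched regions fell in acute NEG (7 regions, -2.46), chronic POS (3, -3.73), chronic NEG (4, -1.48) and POSR (5, -0.66). On chromosome 20 from 36738527 to 36816192, H3K27ac fell in 9 of 10 regions in acute NEG, 10 of 12 in acute POS and 9 of 9 in chronic POS (median -2.35), while in POSR 8 of 9 were higher than in POS (median 0.74). On chromosome 18 from 21405928 to 21465125, all 10 regions were higher in POS than in NEG (median 3.04), and 7 of 7 fell in chronic POS. On chromosome 1 from 103719692 to 103750260, all 6 regions rose in chronic NEG (median 2.12) and 4 of 4 in acute NEG, and the 3 matched regions were higher in NEG than in POS before treatment (-4.50).

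Longer stretches were sought in which at least 90% of 15 neighbouring regions were 2-fold or more higher, or as many lower. POS against NEG had 93 higher and 105 lower, against a mean of 0.58 in shuffled data, and chronic POS had 4 and 11. In POSR against POS, 27 were higher and 2 lower, against none in shuffled data. Of 15 POSR stretches with a median POS level of at most 2.14 CPM and 5 or more regions matched to the POS and NEG table, 12 had a median 2-fold or more higher in NEG, as did 6 of 8 other windows at or under that level. Both comparisons use the same POS libraries. Examples were chromosome 3 from 161367523 to 164973462 (49 of 53 regions, median log2 fold change 1.91, 24 of 25 matched regions higher in NEG) and chromosome X from 141459769 to 147954117 (49 of 51 regions, median 2.80, 9 of 9 higher in NEG). Across the 27 stretches the median share of all regions with a lower POS level was 1.36%, whereas for the stretch of chromosome 12 starting at 24948440 it was 55.1%. In 99 regions more than 16 times as strong in NEG as in POS, the level in POSR relative to NEG had a median of 0.0909 in POSR1 and 0.109 in POSR2, against 0.0436 in POS, and reached 0.476 and 0.484 at the 90th percentile, with tables normalized separately. Because these regions were chosen for a low POS level, they were chosen again on 2 POS libraries at a time, and the POS library left out then had a median of 0.0359, 0.0523 or 0.0440, against 0.0930 to 0.0965 in POSR1 and 0.106 to 0.111 in POSR2. Of the 99 regions, 55 were called higher and 13 lower in POSR than in POS.

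Regions lost after trametinib held JUNB sites of untreated cells, from either POS or NEG, more often than regions gained. Sites 2-fold or more higher in POS did not follow this pattern. For all sites together, the level before treatment is argued against as the whole cause in acute POS. There the odds ratio within 5 level groups was 2.42, and 1.98 (1.73 to 2.27) within 100. In chronic NEG, level alone may account for the pattern, since the matched odds ratio was 0.944, and within 100 groups it was 0.758 (0.613 to 0.936). The intervals of all these odds ratios take regions as independent, although neighbouring regions moved together. They may thus be too narrow, and the direction in chronic NEG is not settled. By a rule set before the data were seen, level is argued against where the interval within 5 groups lies wholly above 1.5. Chronic POS met this rule (2.03, 1.85 to 2.22), but within 100 groups its interval, unlike that of acute POS, reached below 1.5 (1.63, 1.48 to 1.79). Acute NEG did not meet it (1.74, 1.46 to 2.08), with 1.54 (1.28 to 1.84) within 100 groups. In chronic POS and acute NEG the part left by level therefore cannot be told apart from level measured too coarsely. For chronic POS this departs from the rule, by groups chosen after the results were seen. JUNB after treatment was not analysed here, so a loss of JUNB at these regions stays untested.

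Whole chromosomes were shifted between POS and NEG, and a stretch of chromosome 12 between POSR and POS. A few strong regions do not account for the former, as both quartiles moved with the median on 8 of 8 chromosomes, and whole-chromosome shifts are not the whole difference between POS and NEG, as 42682 regions were called with factors per chromosome, among them 39780 of the 43649 called without, in the same direction. The correlation of 0.820 with JUNB sites outside H3K27ac regions is consistent with DNA copy number that differs between POS and NEG, as a hypothesis. On chromosome 12, regions with an above-median POS level were higher in POSR by a median of 2.73 on the log2 scale, but the stretch was chosen for such values, so this decides nothing. DNA copies gained in POSR and activation of the stretch without a gain cannot be told apart there, because counts of the input libraries were not used here.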
